A study of Mus musculus with 13 samples.

How the data were processed

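Total RNA from superior cervical and coeliac ganglia of mice at 2 weeks of age was measured on 1-colour Agilent arrays. Per the labels there were 6 TH-MYCN+/+ and 7 wild-type samples, the wild-type animals were age-matched littermates, RNA was isolated with a column kit and labelled with Cy3. The labels name no batch, day, litter or sex, and the number of arrays limits the precision.

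The deposited values were read as log2 intensities. The base is not given in the sources used here and was inferred from the range, which reached 18.1 to 18.6 on each array and would exceed any scanner as a natural logarithm. Array medians lay between 3.94 and 5.07, so the deposited values were not normalized between arrays. Scanner software, background correction and averaging of replicate probes are not given in the sources used here, and no detection or saturation flags were used.

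The table held 55821 probes, of which 140 were control probes and 55681 were array probes. Symbols were taken from the platform annotation, and 30626 probes carried 1 symbol while 25055 carried none and were left out. A check by Entrez number matched 30332 probes and changed 0 symbols. These probes represented 21893 genes, of which 6807 had several probes, and the probe with the highest mean over all arrays stood for its gene. For 227 genes, probes were called in opposite directions. Because the medians differed, array probes were quantile normalized, and all genes entered the comparison without a filter on intensity. Ssrp1 was to be reported but was not matched, and was not analysed here.

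The background level of an array was the 95th percentile of its 96 ERCC probes. This assumes that no ERCC transcripts were added, which is not given in the sources used here. The spike-in level was the mean of 7 of the 10 E1A probes, those above background on all arrays, which assumes that equal amounts were added. A gene named among the largest changes with any array of its dimmer genotype below background, or any named gene with all of them below, has a bound in place of a fold change. Counts of arrays above background refer to the probe that stands for the gene, except that the filter on 6 or more arrays counts any probe of the gene.

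Genotypes were compared in limma 3.58.1 under R 4.3.3 with a linear model of 1 factor and empirical Bayes moderation, TH-MYCN+/+ minus wild type, two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and 12574 genes had an unadjusted p under 0.05. Normalized values are given as mean and SD, fold changes with their SE. This linear model was also run on simulated data with 50 changed genes per size among 21893. It recovered 20% of log2 changes of 0.5, 66% of 1, 96% of 2 and 98% of 4, with 9 false calls. With so few changed genes the adjusted cutoff was stricter there than in the real comparison.

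Gene lists were written from general knowledge in 4 classes: sympathetic lineage, growth, stress and metabolism, and other cells or neighbouring tissue. Of 41 lists, 40 were tested by camera with a preset correlation of 0.01, adjusted over the lists, and the list of sex-linked genes served only to describe the animals. Camera with an estimated correlation and fry were run beside it. Single measures of arrays were compared by exact permutation over the 1716 splits into 6 and 7, two-sided, where the smallest p is 0.000583, and their intervals are at 95%. The model across genes was also run on 100 of these splits, the real one included.

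The 181 genes named by rule were the 12 largest rises and 12 largest falls among called genes whose symbol is not a clone or model name, up to 4 members with the smallest p of each list or 2 where none passed, and those of 12 fixed genes that were analysed. The text gives values for some of them, and the rest are summarised as counts. The design, the lists, this rule and the first set of alternatives were chosen before the data were examined. That set comprised the replicate number as a block, median centring, centring on the 75th percentile, leaving out the dimmer genes, the mean of all probes of a gene, a trended and robust variance, array weights, leaving out each array in turn, a fold threshold, an exact Wilcoxon test, and both other list tests. Median centring took the place of quantile normalization, which became the main choice. A set of 5 alternatives was added after the data were seen: spike-in scaling, the values as deposited, Xist as a covariate, genes above background on 6 or more arrays, and all arrays but 4 with markers of neighbouring tissue.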

Results

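Gene expression was measured in sympathetic ganglia, the superior cervical and the coeliac, of mice at 2 weeks of age. One group was homozygous for the TH-MYCN transgene, a human MYCN cDNA driven from a tyrosine hydroxylase promoter in a mouse model of neuroblastoma. The other group was wild type at the same age. There were 6 TH-MYCN+/+ and 7 wild-type samples, each hybridised to its own 1-colour Agilent array, and their number limits the precision. The labels do not say whether each array is a separate animal, so p-values measure the spread between these samples, which may be technical in part. The values are taken as log2, a base inferred from their range, and every fold change rests on it. Every array carried values for 55821 probes, and 21893 named genes entered the comparison. Between 56.3% and 63.0% of probes on an array lay above its background level. Arrays of one genotype correlated at 0.989 to 0.994 (TH-MYCN+/+) and 0.979 to 0.992 (wild type) across genes. Arrays of different genotypes correlated at 0.949 to 0.978. The first principal component held 58.4% of the variance and separated the genotypes.

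The comparison asks what the MYCN transgene changes in young sympathetic ganglia. In TH-MYCN+/+ ganglia, genes of mitosis, DNA replication, chromatin assembly, RNA processing and ribosome production rose together, several of them by over 10-fold, and the single neurogenic factors Neurod1 and Nhlh2 rose with them. These 5 lists passed by camera with a preset correlation, but no list passed with an estimated correlation. Th and Dbh, which act in noradrenaline synthesis, fell, as did many markers of mature sympathetic neurons, of Schwann and satellite glia, of endothelium, of fibroblasts and of antigen presentation. These falls are after quantile normalization, and with spike-in scaling 1 of 18 endothelial and 2 of 15 antigen presentation genes were called lower. The medians of both lists stayed negative with that scaling, at -0.45 and -0.69 on the log2 scale. Macrophage markers did not fall as a group. Of 21893 genes, 11652 differed at an adjusted p under 0.05 by limma, with 4136 higher and 7516 lower in TH-MYCN+/+ ganglia. An absolute log2 fold change of at least 1 was reached as well by 1741 higher and 3293 lower genes. The values of the genotypes did not overlap for 7753 genes, where chance gives 0.117% of genes.

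How many of these genes counted as higher depended on the scaling between arrays. Among called genes 35.5% were higher after quantile normalization, 22% after median centring (3026 higher and 10728 lower) and 31.0% after centring on the 75th percentile (3866 higher and 8620 lower). In the values as deposited 66.8% were higher (5521 against 2746 lower), and after scaling to the E1A spike-in probes 78.2% (5675 against 1579 lower). The median gene shifted by -0.15 on the log2 scale after quantile normalization, by -0.44 and -0.30 after the 2 kinds of centring, by 0.14 as deposited and by 0.30 after spike-in scaling. Medians of gene lists are therefore given relative to the median gene, and counts are given with spike-in scaling too where members fell. The spike-in level itself varied between arrays (SD 0.36 in TH-MYCN+/+ and 0.49 in wild type). Scaling to it adds this spread to every gene, so a call lost there need not mean that a fall is absent. Fold changes of single genes are those after quantile normalization.

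Mycn, measured by 1 probe annotated to the mouse gene, stood at 10.26 ± 0.13 (SD, n = 6) in TH-MYCN+/+ and 10.49 ± 0.14 (SD, n = 7) in wild-type ganglia. Its log2 fold change was -0.24 ± 0.08 (SE), with an adjusted p of 0.0248. This call did not hold with spike-in scaling (0.26, adjusted p = 0.467), in the values as deposited (0.10, adjusted p = 0.732), or without TH-MYCN+/+ replicate 3 (-0.20, adjusted p = 0.0612). The transgene is human, so a mouse probe may not report it and does not check the labels.

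The 12 largest rises among called genes, ranked by fitted log2 fold change, were Igfbpl1, Pnoc, Insm1, Ush1c, Slc35f2, Neurod6, Nhlh2, Bcl11a, Cnih3, Cbln2, Drd4 and Phf21b. Insm1, a zinc finger factor of neuroendocrine differentiation, reached 13.50 ± 0.25 (SD, n = 6) against 5.96 ± 0.60 (SD, n = 7), a log2 fold change of 7.54 ± 0.25 (SE) with an adjusted p of 3.67e-10. Pnoc, which encodes the precursor of the neuropeptide nociceptin, was at least 335-fold higher, with 4 of 7 wild-type arrays above background. Igfbpl1, related to insulin-like growth factor binding proteins, was at least 222-fold higher, with 1 of 7 wild-type arrays above background. Slc35f2, a solute carrier, rose from 5.76 ± 0.33 to 12.95 ± 0.23 (SD). Bcl11a, a zinc finger repressor, rose by 6.43 ± 0.61 (SE), and by 4.23 when all its probes were averaged. Nhlh2, a basic helix-loop-helix factor of developing neurons, was at least 57.7-fold higher, with 3 of 7 wild-type arrays above background, and Drd4, a dopamine receptor, at least 28.0-fold, with 2 of 7. Cbln2, a secreted synaptic organiser, was at least 62.2-fold higher, with 6 of 7 wild-type arrays above background, and Phf21b rose by 5.89 ± 0.25 (SE). The other genes of this set were below background on every wild-type array. A gene below background on any wild-type array has a lower bound only, and its rank among the rises is not settled. Ush1c was at least 46.9-fold higher, Neurod6, a neurogenic factor, at least 29.3-fold, and Cnih3, an auxiliary subunit of AMPA receptors, at least 16.4-fold. A bound sets the mean of the brighter group against the dimmer group's mean, in which each value below the array's lowest signal above background is raised to that signal.

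The 12 largest falls, ranked in the same way, were Cma1, Itgb4, Mlip, Sstr2, Krt33b, Mettl24, Mcpt4, Nr0b1, Npr3, Smim5, Tex12 and Dct. Ranks of those below background on any TH-MYCN+/+ array are not settled. The mast cell chymases fell strongly, Mcpt4 by 2.75 ± 0.29 (SE, adjusted p = 5.25e-06), while Cma1 was at least 3.18-fold lower and below background on all 6 TH-MYCN+/+ arrays. Mettl24 was at least 2.19-fold lower, the nuclear receptor Nr0b1 at least 2.54-fold lower and the keratin Krt33b at least 1.29-fold lower, each below background on all TH-MYCN+/+ arrays, and Krt33b was above it on 6 of 7 wild-type arrays. Npr3, the natriuretic peptide clearance receptor, had a log2 fold change of -2.72 ± 0.31 (SE). Dct, a melanin synthesis enzyme, was at least 5.79-fold lower, with 4 of 6 TH-MYCN+/+ arrays above background. The somatostatin receptor Sstr2, above background on 5 of 6, was at least 5.67-fold lower, Mlip, on 3 of 6, at least 5.10-fold, and Smim5, on 2 of 6, at least 5.76-fold. Itgb4, an integrin of epithelial and perineurial cells, had a bound of 7.32-fold lower over all arrays, which rests on TH-MYCN+/+ replicate 2. The value of 3.16 there lay below background, while the other TH-MYCN+/+ arrays held 8.80 to 9.96. Without that array the log2 fold change was -1.90, a smaller fall than the bound. Tex12, a meiotic protein gene, was at least 4.11-fold lower, with 2 of 6 TH-MYCN+/+ arrays above background. Its call ended with the replicate number as a block (adjusted p = 0.0591) and without 4 arrays that carried markers of neighbouring tissue (adjusted p = 0.0932).

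**Figure D1:**
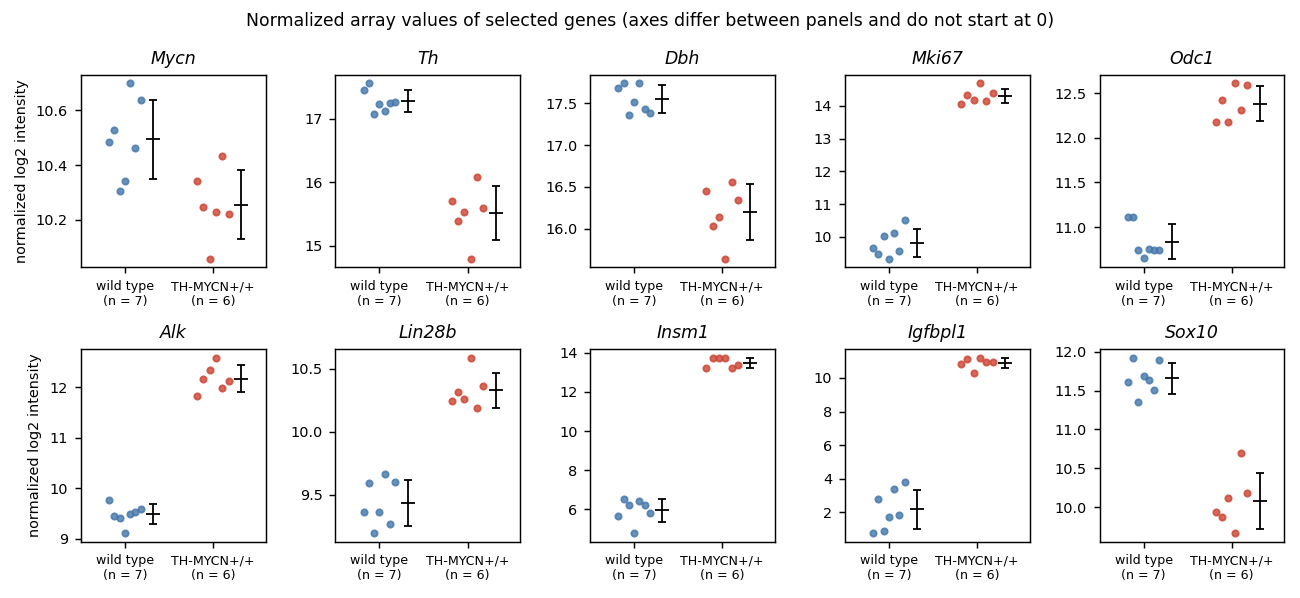
Normalized log2 intensity of 10 genes on each of 7 wild-type (blue) and 6 TH-MYCN+/+ (red) arrays, with the mean and SD beside the points. Mki67, Odc1, Alk, Lin28b, Insm1 and Igfbpl1 are higher and Th, Dbh and Sox10 lower on all TH-MYCN+/+ arrays than on any wild-type array, while the values of Mycn overlap and its fold change turns positive with spike-in scaling.

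Mitosis genes had the highest median of the 40 lists. Of 31 measured mitosis genes 30 rose and none fell, with a median of 4.25 relative to the median gene (camera adjusted p = 4.57e-28). That median was 4.19 without 1 gene below background on all arrays, and with 1 below it in 1 genotype at its bound. With an estimated correlation this list did not pass (adjusted p = 0.112). Ube2c, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, rose 38.9-fold, the mitotic kinesin Kif2c 24.9-fold and the cell cycle factor Mybl2 11.8-fold. Mki67, the proliferation marker, stood at 14.30 ± 0.22 (SD, n = 6) against 9.82 ± 0.42 (SD, n = 7), 22.3-fold higher with an adjusted p of 1.48e-09. All 31 measured genes of DNA replication rose, with a relative median of 3.0 (camera adjusted p = 2.64e-27, and adjusted p = 0.102 with an estimated correlation). Mcm10 rose 39.5-fold, the helicase subunits Mcm2 and Mcm7 rose 16.4-fold and 13-fold, and thymidylate synthase, Tyms, rose 10.3-fold. Among 19 genes of histone chaperones and chromatin 17 rose and none fell, with a relative median of 1.67 (camera adjusted p = 4.14e-13, and adjusted p = 0.102 with an estimated correlation). These included Hmgb2 (22.8-fold), the chromatin assembly subunit Chaf1b (17.8-fold), the histone chaperone Nasp (9.63-fold) and the methyltransferase Ezh2 (8.05-fold). Supt16, a subunit of the FACT histone chaperone, rose 2.12-fold (log2 fold change 1.08 ± 0.19 SE, adjusted p = 3.08e-04).

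The machinery that makes RNA and ribosomes rose by smaller factors. All 21 genes of RNA processing rose, with a relative median of 1.40 (camera adjusted p = 6.10e-14, and adjusted p = 0.102 with an estimated correlation), among them the RNA-binding proteins Hnrnpab (3.60-fold) and Hnrnpa1 (3.07-fold) and the splicing factor Sf3a3 (2.23-fold). Of 38 genes of ribosome biogenesis 33 rose and 1 fell, with a relative median of 1.01 (camera adjusted p = 5.39e-15, and adjusted p = 0.112 with an estimated correlation). With spike-in scaling 34 rose and none fell. The nucleolar proteins Nop56 and Nop58 rose 3.20-fold and 3.16-fold, and Ppan rose 3.66-fold. Of 37 ribosomal protein genes 31 rose and 1 fell, with a relative median of 0.47 (camera adjusted p = 7.41e-10, and adjusted p = 0.159 with an estimated correlation). Adjusted over the list alone, 32 rose, after median centring 15 rose, and with spike-in scaling 36 rose and none fell. Rpl8 rose 1.67-fold and Rplp0 1.65-fold, from levels close to the top of the measured range. In nucleotide and one-carbon metabolism 14 of 27 genes rose and 5 fell (17 rose and 5 fell adjusted over the list alone), with a relative median of 0.42 (camera adjusted p = 9.71e-05, and adjusted p = 0.205 with an estimated correlation). With spike-in scaling 19 rose and none fell, and after median centring 9 rose and 5 fell. Thymidine kinase, Tk1, rose 9.94-fold, the dUTPase Dut 6.64-fold and the serine synthesis enzyme Psat1 2.51-fold.

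Translation factors and mitochondrial protein import moved less. Of 21 genes of translation initiation, elongation and tRNA charging 9 rose and 4 fell (10 and 5 adjusted over the list alone), with a relative median of 0.39 (camera adjusted p = 0.0383, and adjusted p = 0.462 with an estimated correlation). With spike-in scaling 11 rose and none fell. Eif4a1, a helicase of translation initiation, rose 1.73-fold and Pabpc1, which binds poly(A) tails, 1.65-fold. This list no longer passed without wild-type replicate 3 (adjusted p = 0.0554), replicate 4 (0.0664) or replicate 7 (0.0507), with the replicate block (0.0580), with either kind of centring (0.142 and 0.0747), with the dimmer genes left out (0.0612), with the mean of all probes (0.0518), or among genes above background on 6 or more arrays (0.0617). Of 24 genes of mitochondrial translation and import 9 rose and 3 fell, with a relative median of 0.27 (camera adjusted p = 0.0309, and adjusted p = 0.462 with an estimated correlation). With spike-in scaling 10 rose and none fell. Timm10, an import chaperone, fell 1.87-fold, a call that ended with spike-in scaling (adjusted p = 0.191). The list no longer passed after median centring (adjusted p = 0.293), after centring on the 75th percentile (0.158), with the dimmer genes left out (0.0629), as deposited (0.0609) or among genes above background on 6 or more arrays (0.0571), while its relative median stayed positive in each. Odc1, the rate-limiting enzyme of polyamine synthesis, rose 2.91-fold (log2 fold change 1.54 ± 0.11 SE, adjusted p = 1.88e-07). The 16 genes of the polyamine pathway did not shift together, with 4 up and 10 down (11 down adjusted over the list alone; camera adjusted p = 0.328). With spike-in scaling 4 of these were up and 1 was down.

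**Figure D2:**
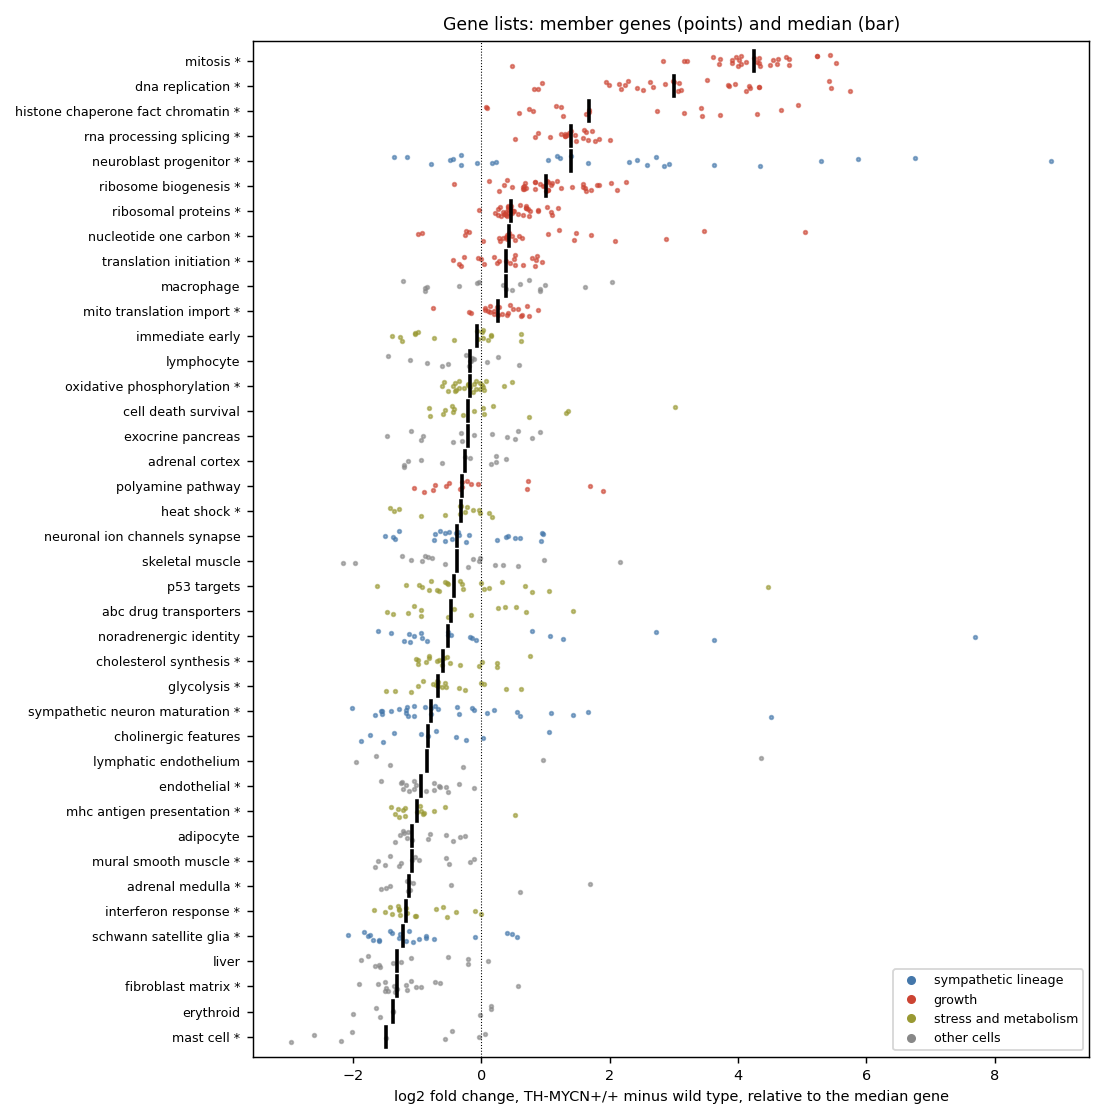
Log2 fold change of each member gene (points) of 40 gene lists, TH-MYCN+/+ minus wild type, relative to the median of all genes, with the list's median as a bar and an asterisk where camera with a preset correlation passed. Mitosis genes lie highest, with a median of 4.25, and mast cell markers lowest, at -1.49, and no list passed with an estimated correlation.

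The sympathetic lineage held both rises and falls. Th, the rate-limiting enzyme of catecholamine synthesis, stood at 15.51 ± 0.42 (SD, n = 6) against 17.28 ± 0.17 (SD, n = 7), 3.39-fold lower with an adjusted p of 2.43e-06. Dbh, which makes noradrenaline, was 2.56-fold lower (log2 fold change -1.35 ± 0.14 SE, adjusted p = 4.37e-06). Both lie near the top of the measured range, where no saturation flags were used and a difference could be compressed. Among 21 genes of noradrenergic identity 13 fell and 6 rose, and with spike-in scaling 5 fell and 6 rose. Insm1, Dlk1, which encodes a Notch ligand family protein (11.1-fold), and Sox11, a transcription factor of immature neurons (5.97-fold), were among those that rose. The list as a whole did not pass (camera adjusted p = 0.451), and its relative median of -0.52 and relative mean of 0.22 differ in sign. Of 30 genes of sympathetic neuron maturation 20 fell and 5 rose, with a relative median of -0.78 (camera adjusted p = 0.0250, and adjusted p = 0.465 with an estimated correlation). It did not pass with the dimmer genes left out (0.0791) or among genes above background on 6 or more arrays (0.0624). With spike-in scaling 10 fell and 6 rose. Sncg, a synuclein of peripheral neurons, fell 4.47-fold and the heavy neurofilament Nefh 2.50-fold, while the medium neurofilament Nefm rose 2.84-fold and the neuropeptide precursor Cartpt 20.6-fold.

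Neuroblast and progenitor genes rose as a list. Of 27 measured genes 16 rose and 8 fell, with a relative median of 1.39, or 1.23 with genes below background at their bound (camera adjusted p = 7.13e-06, and adjusted p = 0.159 with an estimated correlation). With spike-in scaling 17 rose and 2 fell, and as deposited 17 rose and 3 fell. Neurod1, a neurogenic factor, was at least 15.1-fold higher, and Birc5, a survival and cell division protein also in the mitosis list, rose 18.2-fold. Alk, a receptor tyrosine kinase mutated in some neuroblastomas, stood at 12.17 ± 0.27 (SD, n = 6) against 9.48 ± 0.20 (SD, n = 7), 6.46-fold higher with an adjusted p of 4.85e-09. Lin28b, an RNA-binding regulator of let-7 microRNAs, rose 1.86-fold (adjusted p = 5.48e-06). The 8 genes that fell included Sox2, at -1.51 on the log2 scale, and Prom1, at -1.31, both chosen after their values were seen. The rise therefore does not hold for every progenitor marker of the list. Neuronal ion channel and synapse genes did not pass as a list (camera adjusted p = 0.135), although 14 of 24 fell and 1 rose (16 and 2 adjusted over the list alone), and with spike-in scaling 4 fell and 7 rose. The potassium channel Kcna2 fell 3.15-fold and the glutamate receptor Gria1 2.82-fold. Cholinergic genes did not pass either (camera adjusted p = 0.199), with 6 of 11 down and 1 up (7 down adjusted over the list alone), and with 3 down and 1 up after spike-in scaling. The cholinergic list did pass relative to other genes with that scaling (adjusted p = 0.0155) and as deposited (0.0474). By camera with an estimated correlation after quantile normalization its adjusted p was 0.537. Ache, acetylcholinesterase, fell 3.20-fold and the choline transporter Slc5a7 3.68-fold.

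Glial markers fell with the neuronal maturation genes. Of 22 markers of Schwann cells and satellite glia 18 fell and 1 rose, with a relative median of -1.22 (camera adjusted p = 2.72e-04, and adjusted p = 0.357 with an estimated correlation). With spike-in scaling 12 fell and 3 rose. Sox10, the transcription factor of neural crest glia, fell 2.99-fold, the glial calcium-binding protein S100b 3.94-fold, and the myelin genes Mag and Cnp 4.69-fold and 3.35-fold.

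The lists of glycolysis, oxidative phosphorylation, cholesterol synthesis and heat shock were lower relative to other genes after quantile normalization. In glycolysis 15 of 19 genes fell and 1 rose, with a relative median of -0.67 (camera adjusted p = 7.99e-04, and adjusted p = 0.357 with an estimated correlation). With spike-in scaling 2 fell and 2 rose. The neuronal enolase Eno2 fell 3.10-fold, while the 2.39-fold fall of Aldoa, an aldolase, did not pass with spike-in scaling (adjusted p = 0.0963). Among 25 genes of oxidative phosphorylation 15 fell and 1 rose (18 fell adjusted over the list alone), with a relative median of -0.19 (camera adjusted p = 0.0152, and adjusted p = 0.462 with an estimated correlation). With spike-in scaling none of these fell and 1 rose, and the list's own median turned from -0.34 to 0.26. This list did not pass with spike-in scaling (0.813), as deposited (0.617), after median centring (0.0877), with the dimmer genes left out (0.0612), with the mean of all probes (0.0501) or among genes above background on 6 or more arrays (0.0617). The succinate dehydrogenase subunit Sdhb, 1.65-fold lower, was at -0.07 with that scaling (adjusted p = 0.825). Of 18 genes of cholesterol synthesis 13 fell and 1 rose, with a relative median of -0.60 (camera adjusted p = 0.0152, and adjusted p = 0.502 with an estimated correlation), and with spike-in scaling none fell. It did not pass among genes above background on 6 or more arrays (0.0543). Hmgcs1, an early enzyme of this pathway, was 2.20-fold lower, and -0.45 with spike-in scaling (adjusted p = 0.221). Heat shock and unfolded protein genes fell at 10 of 15 and rose at none, with a relative median of -0.32 (camera adjusted p = 0.0160, and adjusted p = 0.205 with an estimated correlation). Spike-in scaling left 3 down and 1 up and turned this list's own median from -0.47 to 0.12, and the list did not pass with that scaling (0.0883), as deposited (0.0958), with the dimmer genes left out (0.0700) or among genes above background on 6 or more arrays (0.0571). The small chaperones Hspb8 and Hspb1 fell 2.98-fold and 2.70-fold, and Hspa1a 2.84-fold.

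Other lists of stress and metabolism held changes in both directions and did not pass. Among 22 targets of p53, 12 fell and 4 rose (13 fell adjusted over the list alone; camera adjusted p = 0.322), and with spike-in scaling 2 fell and 5 rose. Cdkn1a, a cyclin-dependent kinase inhibitor, fell 1.80-fold with an adjusted p of 2.54e-04, but did not pass with spike-in scaling (-0.34, adjusted p = 0.284) or when its 3 probes were averaged (-0.26, adjusted p = 0.387). Perp, a membrane protein, fell 3.44-fold, and Gtse1, which also acts in the cell cycle, was at least 6.82-fold higher. Of 16 genes of cell death and survival 8 fell and 3 rose (9 fell adjusted over the list alone; camera adjusted p = 0.555), with a relative median of -0.21 and a relative mean of 0.12, which differ in sign. With spike-in scaling none of the 16 fell and 4 rose. Hrk, a BH3-only activator of apoptosis, rose 7.28-fold. Of 14 ABC transporters 9 fell and 3 rose (camera adjusted p = 0.328), and 3 fell and 4 rose with spike-in scaling. The drug exporter Abcb1a fell 2.88-fold while Abcc3 rose 2.41-fold. Of 18 immediate early genes 8 fell and 1 rose (camera adjusted p = 0.208), and 2 fell and 2 rose with spike-in scaling. Fosb fell 2.90-fold and Arc 2.60-fold.

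Genes of interferon response and antigen presentation were lower. Among 18 interferon response genes 16 fell and none rose, with a relative median of -1.17 (camera adjusted p = 2.57e-04, and adjusted p = 0.384 with an estimated correlation), and 7 fell with spike-in scaling. Xaf1 fell 2.74-fold and Oasl2 2.51-fold. Of 15 genes of antigen presentation 14 fell and none rose, with a relative median of -1.0 (camera adjusted p = 0.00343, and adjusted p = 0.462 with an estimated correlation), and 2 fell with spike-in scaling. The list's mean was highest on wild-type replicate 3, at 10.89, where lymphocyte markers were high too, and was 9.69 to 10.27 on the other wild-type arrays. It was 8.72 to 9.51 on TH-MYCN+/+ arrays, highest on replicate 5, which had the most lymphocyte signal of that genotype. B2m, the light chain of MHC class I, fell 2.71-fold and the immunoproteasome subunit Psmb8 2.72-fold.

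Markers of several other cell types were lower on the TH-MYCN+/+ arrays. Of 18 endothelial markers 17 fell, with a relative median of -0.94 (camera adjusted p = 2.57e-04, and adjusted p = 0.357 with an estimated correlation), among them Vwf, 3.29-fold lower, and with spike-in scaling 1 fell. Of 18 fibroblast and matrix genes 17 fell and 1 rose, with a relative median of -1.32 (camera adjusted p = 2.75e-05, and adjusted p = 0.384 with an estimated correlation), and 12 fell with spike-in scaling. The collagens Col1a2 and Col6a1 fell 3.13-fold and 2.80-fold, and the receptor Pdgfra 3.38-fold. Of 13 mural and smooth muscle markers 9 fell, with a relative median of -1.09 (camera adjusted p = 0.00741, and adjusted p = 0.384 with an estimated correlation), and 4 fell with spike-in scaling. That median was -1.17 without 1 marker below background on all arrays, and with 1 below it in 1 genotype at its bound. The list did not pass with the dimmer genes left out (0.0612). Cspg4, a pericyte proteoglycan, fell 3.14-fold and the actin-binding protein Tagln 2.98-fold. Of 9 mast cell markers 7 fell, with a relative median of -1.49 (camera adjusted p = 0.0330, and adjusted p = 0.357 with an estimated correlation), among them Hdc, which makes histamine, 3.11-fold lower. Without the 4 arrays with markers of neighbouring tissue the mast cell list had an adjusted p of 0.0578, among genes above background on 6 or more arrays 0.0680, and 4 of its genes fell with spike-in scaling.

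Macrophage markers did not shift as a group (camera adjusted p = 0.185). Of 17 markers 7 rose and 4 fell, with a relative median of 0.38, and with spike-in scaling 8 rose and 1 fell. The lysosomal protein Cd68 rose 2.75-fold and the complement subunit C1qc 1.70-fold, while Mrc1, the mannose receptor of resident macrophages, fell 2.59-fold. Globin and other red cell genes fell at 5 of 8 and rose at none, without passing as a list (camera adjusted p = 0.0563, and adjusted p = 0.462 with an estimated correlation). That list passed without TH-MYCN+/+ replicate 6 (adjusted p = 0.0468), wild-type replicate 2 (0.0384) or wild-type replicate 3 (0.0482), with spike-in scaling (0.00196), as deposited (0.00804), after either kind of centring (0.0386 and 0.0446), with array weights (0.0435), or without the 4 arrays (0.0368). With spike-in scaling 5 of its genes fell and 1 rose. Hba-a1 was 4.43-fold lower. Of 11 genes of the adrenal medulla, 7 of which stand in another list too, 9 fell and 2 rose, with a relative median of -1.13 (camera adjusted p = 0.0291, and adjusted p = 0.462 with an estimated correlation). Pnmt, which makes adrenaline, rose 2.92-fold, whereas the prohormone convertase Pcsk1 fell 3.11-fold, and 5 genes fell with spike-in scaling. The list did not pass after median centring (0.0524) or among genes above background on 6 or more arrays (0.0624).

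Markers of tissues that lie beside the ganglia were high on single arrays. The mean of 14 lymphocyte markers was 9.06 on wild-type replicate 3 and 4.2 to 4.65 on the other wild-type arrays, and 6.41 on TH-MYCN+/+ replicate 5. Skeletal muscle markers averaged 10.98 on TH-MYCN+/+ replicate 6 and at most 7.89 on any other array. Markers of liver and adrenal cortex were highest on wild-type replicate 1, at 8.28 and 6.89. None of these lists passed by camera after quantile normalization, with adjusted p of 1.0 for lymphocytes (0 up and 1 down of 14), 0.799 for skeletal muscle (1 up and 2 down of 18), 0.138 for liver (5 down of 12, and 4 adjusted over the list alone), 0.892 for adrenal cortex (0 of 11) and 0.799 for exocrine pancreas (5 down of 14). With spike-in scaling 1 liver marker fell and none rose, 1 pancreas marker fell and 3 rose, 1 muscle marker fell and 1 rose, and 1 lymphocyte and 1 adrenal cortex marker rose. The liver list passed relative to other genes with the replicate block (adjusted p = 0.0473), with spike-in scaling (0.00440) and as deposited (0.0214). By camera with an estimated correlation after quantile normalization its adjusted p was 0.628. The relative medians of skeletal muscle (-0.38) and adrenal cortex (-0.25) were negative while camera's direction was up. Adipocyte markers fell at 7 of 13, and at 8 adjusted over the list alone (camera adjusted p = 0.123, and adjusted p = 0.628 with an estimated correlation). Without TH-MYCN+/+ replicate 2 this list passed (adjusted p = 0.00112), as it did with spike-in scaling (0.00157) and as deposited (0.00653), although none of its 13 genes passed under either scaling. Adipoq, at -1.50 over all arrays, did not pass with spike-in scaling (adjusted p = 0.0639). Of 6 lymphatic endothelial markers 2 rose and 1 fell (3 fell adjusted over the list alone; camera adjusted p = 0.555), with a relative median of -0.85, or -1.43 without 1 marker below background on all arrays, where camera's direction was up. With spike-in scaling 2 rose and 1 fell. Its largest rise was in Prox1, 18.5-fold, which is also a transcription factor of neural progenitors. Xist, expressed in females, was above background on 1 of 6 TH-MYCN+/+ and 2 of 7 wild-type arrays.

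**Figure D3:**
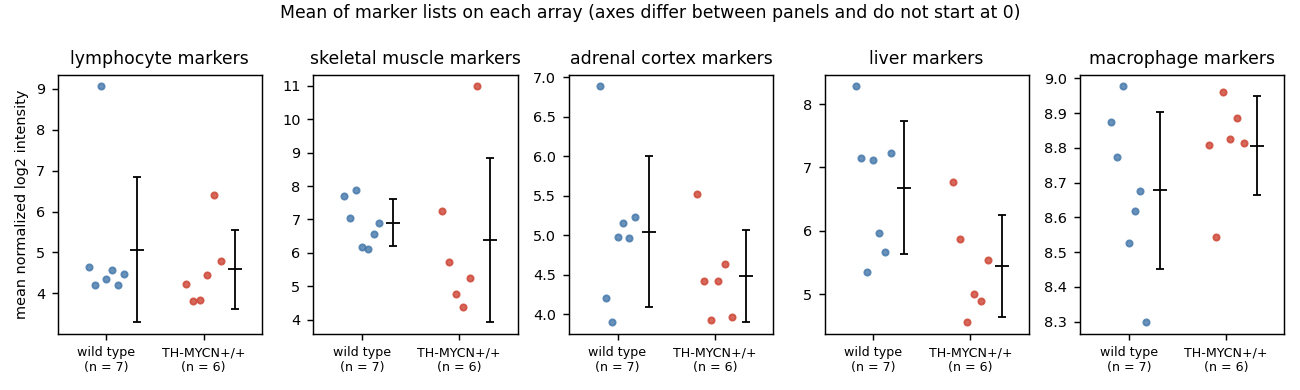
Mean normalized log2 intensity of marker lists on each of 7 wild-type (blue) and 6 TH-MYCN+/+ (red) arrays, with the group mean and SD. Single arrays stand apart, such as wild-type replicate 3 at 9.06 for lymphocyte markers and TH-MYCN+/+ replicate 6 at 10.98 for skeletal muscle markers.

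Without 4 arrays where such markers stood high, TH-MYCN+/+ replicates 5 and 6 and wild-type replicates 1 and 3, 10536 genes were called (3736 higher and 6800 lower), and 10 lists moved up and 13 down. TH-MYCN+/+ replicate 2, where 8 of 13 adipocyte markers had their highest value, was kept in that comparison. Of 40 lists tested, camera with a preset correlation called 23, of which 10 moved up and 13 down relative to other genes, and none of the 23 held with an estimated correlation. By fry, which tests whether the genes of a list move one way on balance, 34 lists passed. For 28 of the 40 lists the counts were the same when adjusted over the list alone. Differences in composition between the ganglia of both genotypes were not measured apart from these markers, and the labels do not tell superior cervical from coeliac ganglia on an array.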

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

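The tests of spike-in levels, of macrophage against other markers, without 4 arrays, and of marker counts on single arrays were chosen after the results were seen, while the counts over other splits of the arrays were planned. Among 446 groups of arrays examined, 27 held an array far from the rest, where chance at about 1 in 20 gives 22.3.

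Of 100 splits of the 13 arrays into 6 and 7, 1 split, the real one, gave as many called genes. It gave 11652, and the highest other gave 9691, from a split that kept all 6 TH-MYCN+/+ arrays in 1 group. This argues against chance for the number of genes, although 100 splits cannot show a share below 1 in 100. For the number of lists 10 of the 100 splits gave as many. The real split gave 23 and the highest other gave 24. The other splits with as many all held more or fewer than 3 TH-MYCN+/+ arrays in the group of 6. With 3 there, no split gave more than 17 lists. Uneven splits keep part of the genotype difference, so this test cannot decide on chance for the number of lists.

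Several named genes had a single distant array, where highest and lowest are meant among arrays of the same genotype. Igfbpl1 was lowest at 10.32 on TH-MYCN+/+ replicate 3, where the other TH-MYCN+/+ arrays held 10.86 to 11.17, and Sstr2 was lowest there too at 0.89 against 3.89 to 4.23. Pnmt was highest on that array at 8.38, against 7.79 to 7.94. On wild-type replicate 6, Neurod6 stood at 2.13 and Cnih3 at 2.45, both near background, while Tpsab1 was lowest there at 0.78. Itgb4 fell to 3.16 on TH-MYCN+/+ replicate 2, Cplx1 reached 12.79 on replicate 5, Hspd1 14.45 on replicate 4 and Krt33b 1.75 on replicate 1. Fosb was highest on wild-type replicate 2 at 6.94, and Vwf on wild-type replicate 5 at 11.95. Among wild-type arrays Pdgfra was lowest on replicate 7 at 8.71. Nlrc5 was lowest on TH-MYCN+/+ replicate 4 at 6.10, and Tpsab1 reached 1.80 on TH-MYCN+/+ replicate 6. Among TH-MYCN+/+ arrays the mean of mural and smooth muscle markers was highest on replicate 6 at 6.72, and that of macrophage markers lowest on replicate 2 at 8.54. No explanation of these values was tested.

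On TH-MYCN+/+ replicate 5 the Y-linked genes Kdm5d and Eif2s3y stood at 0.78 and 3.35, where the other TH-MYCN+/+ arrays held 3.99 to 4.95 and 10.30 to 10.63. The mean of the sex-linked list was 3.80 there, and Xist was at 10.12. Wild-type replicates 2 and 4 had Xist at 8.90 and 8.67, so both genotypes included arrays with Xist.

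Markers of neighbouring tissue stood high on single arrays. Lymphocyte markers averaged 9.06 on wild-type replicate 3, where 13 of 14 measured markers had their highest value of all arrays. Skeletal muscle may be part of TH-MYCN+/+ replicate 6, where 15 of 18 muscle markers had theirs. The most abundant markers, chosen after their values were seen, were Cd79b (11.97, other arrays 4.59 to 9.16), Ccr7 (10.67, others 3.87 to 7.38) and Ms4a1 (10.66, others 1.0 to 7.24) on the former, and Myh8 (15.74, others 6.06 to 11.62), Myh4 (15.18, others 4.03 to 10.32) and Tnnc2 (14.58, others 6.42 to 11.41) on the latter. Of the lymphocyte markers 9, and of the muscle markers 14, were above background on all wild-type arrays, and 0 of either stand in another list. A candidate source on wild-type replicate 3 is lymph node tissue taken with the ganglion, and no biological explanation was tested.

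The same wild-type replicate 3 also held distant values of Bcl11a (7.87, others 3.06 to 4.35), Nlrc5 (9.07), Myh2 (9.38), Eno2 (13.69, others 13.96 to 14.12) and Atp5g1 (15.03). Exocrine pancreas markers averaged 4.55 on wild-type replicate 1, where 6 of 14 peaked, with 9 of 12 liver markers and 7 of 11 of adrenal cortex. Adipocyte markers peaked on TH-MYCN+/+ replicate 2 at 8 of 13.

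Markers of endothelium, fibroblasts, glia and mural cells fell relative to the median gene, while macrophage markers did not. Per array, macrophage markers minus the mean of the 4 other lists were 0.75 ± 0.27 (SD, n = 6) in TH-MYCN+/+ and -0.56 ± 0.25 (SD, n = 7) in wild-type ganglia, a difference of 1.31 (0.99 to 1.63, exact permutation p = 0.000583, the smallest possible). The macrophage list was picked because it had been seen not to fall, so this p cannot decide on dilution of all other cell types by 1 factor. Its markers also disagreed, with 7 of 17 up and 4 down, Mrc1 and Adgre1 among those down. Neighbouring tissue on 4 single arrays is argued against, since without them 4 of 4 lists kept at least 50% of their relative median. These medians were -1.0, -1.50, -1.33 and -1.37. More macrophages, a change within them, or a lower share of the other types may each contribute, and the genotype stays open as a biological explanation.

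The share of higher genes among those called depended on the scaling between arrays. Brighter TH-MYCN+/+ arrays would raise the E1A spike-in level, which differed by -0.16 (-0.70 to 0.37, exact permutation p = 0.524), while in the deposited values the median gene differed by 0.32 (-0.07 to 0.68, p = 0.0932 by the same exact test), the median of all probes by 0.58 (0.32 to 0.84, p = 0.00117) and the upper quartile by 0.45 (0.09 to 0.79, p = 0.0210). More messenger RNA per unit of labelled RNA would raise the median gene against the spike-ins, which differed by 0.48 (-0.02 to 0.99, exact permutation p = 0.0594). Both cannot be told apart here, because the intervals of both spike-in comparisons include 0. The ERCC background was higher on TH-MYCN+/+ arrays by 0.92 (0.41 to 1.38, exact permutation p = 0.00408), so that the dim end of the scale differed between genotypes as well.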

How the results depend on the processing

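The scalings to the spike-ins and as deposited, the Xist covariate, the filter on background and the comparison without 4 arrays were chosen after the data were seen. Every alternative chosen beforehand was run. Of the counts, 144 stayed within 1.5 times their value and 11 did not. Named genes kept direction and call in 4374 comparisons, lost the call in 82, gained one in 14 and reversed in 8. For gene lists these were 990, 55 and 28, with none reversed.

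The number of genes differing between TH-MYCN+/+ and wild-type ganglia was 11652. It was 13754 after median centring, 12486 after centring on the 75th percentile, 11465 with the mean of all probes, 11649 with a trended and robust variance, 11974 with array weights, 11477 by the exact Wilcoxon test, 11451 with the Xist covariate and 11189 for genes above background on 6 or more arrays. With the dimmer genes left out, 10946 were tested and 8171 called, and 977 higher and 1750 lower genes then reached a log2 fold change of 1, fewer because fewer genes were tested.

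With the replicate number as a replicate block, 10537 genes were called, with 9 lists up and 14 down. The numbers do not pair the samples by the values. TH-MYCN+/+ and wild-type arrays of the same number correlated at 0.05, -0.02, -0.08, -0.01, -0.13 and -0.09 after removal of the genotype means, and none correlated best with its own number.

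Among the alternatives run, spike-in scaling moved the number of called genes most. With spike-in scaling 7254 genes were called, 1579 of them lower, and 4033 higher and 719 lower genes reached a log2 fold change of 1. In the values as deposited 2746 were lower, and 3202 higher and 1232 lower genes reached it. Mycn reversed to 0.26 (adjusted p = 0.467) with spike-in scaling and to 0.10 (adjusted p = 0.732) as deposited. With spike-in scaling, Oaz2 (0.026), Eif5b (0.14), Atp5b (0.16), Ndufv1 (0.048) and Amy2a5 (0.058) also reversed, and none of these was called there. Atp5g1 was at 0.036 with the mean of all its probes, not called. The cause was not tested.

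Camera called 23 lists, 15 among genes above background on 6 or more arrays, and 0 with an estimated correlation, where fry called 34. The camera runs with preset and estimated correlation used the same fit and lists. Estimating the correlation also lowers the degrees of freedom of the test, and the part of each in the lost calls was not separated. The correlation was estimated at 0.014 (polyamine pathway) to 0.76 (skeletal muscle), and 0.60 for mitosis, against the preset 0.01. Fry does not compare a list with other genes, and 11652 of 21893 genes were called. Fewer genes were tested under the filter, and otherwise the cause of its lower count was not tested.

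Leaving out each array in turn gave 10944 to 11787 called genes, 3795 to 4138 higher and 7149 to 7690 lower, with 1601 to 1789 and 2958 to 3420 reaching a log2 fold change of 1 up and down. Called lists numbered 22 to 24. Mycn ranged from -0.28 to -0.20, and the call ended without TH-MYCN+/+ replicate 3 (adjusted p = 0.0612).

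Signal over background limits the dim genes. Between 56.3% and 63.0% of probes on an array lay above background, and fold changes of genes below it in 1 genotype are bounds. Changes of 0.5 on the log2 scale were recovered for 20% of simulated genes. The simulation changed only 50 genes per size among 21893, so its adjusted cutoff was stricter than with the 11652 genes called here. Small changes can be missed, but the simulation does not give the share missed in these data.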

Other observations

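Gene families by symbol were examined after the data were seen, 255 families with 10 or more genes, and their tests were all chosen after the results. By camera with a preset correlation 40 passed, 24 up and 16 down relative to other genes, and 0 with an estimated correlation. Many of these overlap the lists of the report.

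Nuclear pore genes rose, a family outside the lists. Of 20 Nup genes 16 rose and none fell, with a median of 1.11 relative to the median gene (camera adjusted p = 6.82e-08, and adjusted p = 0.424 with an estimated correlation). After median centring 13 rose and 1 fell, and with spike-in scaling 17 rose. Nup210 rose by 2.52 and Nup205 by 1.94 on the log2 scale, while Nup50 was at -0.18, not called. The CCR4-NOT deadenylase genes rose too, at 10 of 11 Cnot members (relative median 0.76, camera adjusted p = 1.39e-04, and 0.424 with an estimated correlation), with 5 after median centring and 11 with spike-in scaling. Cnot6 rose by 1.28.

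The Rab, integrin alpha and annexin families fell relative to the median gene, while other families of traffic and adhesion, such as Vps (camera adjusted p = 0.118) and Cdh (0.483), did not pass. Of 72 Rab genes 52 fell and 3 rose, with a relative median of -0.46 (camera adjusted p = 7.85e-05, and 0.560 with an estimated correlation), but with spike-in scaling 10 fell and 4 rose. Of 12 integrin alpha genes 11 fell (relative median -0.93, camera adjusted p = 0.00814, and 0.560 with an estimated correlation), 3 with spike-in scaling. Of 12 annexin genes 10 fell (relative median -1.13, camera adjusted p = 0.00542, and 0.560 with an estimated correlation), 5 with spike-in scaling. Anxa2 fell by 1.43 and Anxa5 by 1.54.

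The G protein gamma and sodium channel families fell too, while Cacna, Kcnj, Kcnk, Syt and Htr did not pass. Of 10 G protein gamma genes 9 fell (camera adjusted p = 0.00840, and 0.560 with an estimated correlation), 5 with spike-in scaling. Of 11 sodium channel genes 9 fell (camera adjusted p = 0.0267, and 0.595 with an estimated correlation), and with spike-in scaling 5 fell and 1 rose. Scn7a fell by 2.01, Scn10a by 1.66 and Scn11a by 1.52, while Scn8a, at 0.80, was not called. Members named here were chosen after their values were seen.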
